A study of Mus musculus with 10 samples.

How the data were processed

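RNA from skeletal muscle of mice was sequenced as total RNA and as RNA recovered by immunoprecipitation (IP) with an antibody against IMP2, the RNA-binding protein encoded by Igf2bp2. Of the 10 libraries, 3 were total RNA of wild-type (WT) muscle, 3 total RNA of knockout (KO) muscle, 2 IP of WT muscle and 2 IP of KO muscle. Per the labels' protocols, the mice were male C57BL/6, a home-made antibody was used for the IP, and libraries were made with a TruSeq kit. The part of Igf2bp2 removed in the knockout was not given in the sources used here.

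Per the submitters' processing notes, STAR and HTSeq were used with mm10 / GRCm38. The deposited files hold 1 count of reads per Ensembl gene and library, as deposited by the authors. The values are whole numbers with a different total in each library, as in unscaled counts. Versions, annotation release, strand setting and read filters were not given in the sources used here, so reads of a gene and of an antisense partner may not be separated. Each file had 43629 genes and 5 lines for reads given to no gene. Symbols were found for 42462 genes, and the 1167 without a symbol held at most 0.129% of a library's counts. Reads aligned to several places made up 26.1% to 43.3% of all reads, reads outside genes 8.54% to 11.2% and ambiguous reads 3.30% to 6.03%. All 37 mitochondrially encoded genes had 0 counts in every library, so their transcripts were not analysed here. Whether their reads had been removed or not matched is not said in the sources used here.

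Reads assigned to genes came to 14809788, 13934240 and 12299030 in WT total RNA, 9691580, 10689583 and 10739792 in KO total RNA, 2159115 and 2547124 in WT IP, and 917462 and 4037480 in KO IP. A count of 0 allows up to 3 counts, which is 0.203 to 0.310 CPM (counts relative to library size) in a total RNA library and 0.743 to 3.27 CPM in an IP library. Where every library of a group was at 0, a fold bound was taken from 3 counts over the whole group. Intervals of ratios are exact Poisson intervals at 95%, and intervals and floors cover counting error only. These ratios and fold bounds use pooled counts and library size alone, without TMM factors. For IP against total RNA, that scaling moved the median log2 of all genes by 0.43 in KO and 0.05 in WT. The ratios are therefore not on the scale of the tests.

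The tests, samples, named genes and gene lists were fixed before the data were examined. Genes were filtered with filterByExpr, scaled with TMM factors, and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with group as the only term and Benjamini-Hochberg adjustment at 0.05. KO was compared with WT in the 6 total RNA libraries. WT was compared with KO in the 4 IP libraries. A fit of all 10 libraries gave IP against total RNA in each genotype and the difference between these contrasts (the interaction). Standard errors (SE) of log2 fold changes were derived from the F statistic. Mean levels are CPM with TMM factors, with the standard deviation (SD) between libraries.

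Named genes were Igf2bp1, Igf2bp2, Igf2bp3, Igf2, H19, Igf1, Igf1r, Ppara and Hmga2 in every comparison. Added to these were up to 10 genes with the largest change in each direction among genes that passed the test, had a mean of at least 1 CPM and did not overlap between groups. Where none passed in a direction, the 5 genes with the smallest p were taken among those that met the same conditions of level and overlap. Genes without a symbol or with clone-based or pseudogene names were left out of these choices. Of each described list, up to 4 members with the smallest p were named. A total of 45 lists with 785 symbols, of which 781 were found (Mrpl33, Wisp2, Ahsp and Rn45s were not), covered muscle fibre, metabolic, ribosomal, growth and stress genes and markers of other cell types. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the lists. For the IP transcripts examined in total RNA, the 200 with the largest positive signed F statistic in the IP comparison were to be used where fewer than 20 passed.

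Simulated counts with known changes were drawn gene by gene from the fitted dispersions. Shifts shared by many genes of a library were not simulated, so recovery in the real data may be lower. Unchanged genes made up 13 of 140 calls for total RNA, 7 of 107 for the IP comparison and 5 of 50 for the interaction. For IP against total RNA they made up 7 of 86 in WT and 3 of 94 in KO. The share of changed genes recovered was 41.2% at 2-fold and 94.6% at 4-fold for total RNA (13014 genes). It was 24.5% and 79.4% for the IP comparison (10389 genes), 5.10% and 40.8% for the interaction (14005 genes), 16.5% and 64.3% for WT IP against total RNA (13942 genes), and 18.9% and 74.5% for KO IP against total RNA (13977 genes). For IP against total RNA the real data gave 5325 calls in WT and 5251 in KO, far more than the simulations. Benjamini-Hochberg adjustment depends on how many genes change, so recovery in these contrasts may be higher or lower than simulated.

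Alternatives were RLE size factors, library size alone, no filter on low counts, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, all 10 libraries together, a replicate block, each library left out in turn, and, for lists, camera with an estimated correlation and fry. A robust fit, a fit without the WT total RNA library 2 and the KO total RNA library 1, and alternatives for lists in the IP comparisons within and between genotypes were added after the data were seen. Coordinates are from the GRCm38 annotation.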

Results

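The study asked what IMP2, an mRNA-binding protein that acts on Igf2 and other transcripts, does in adult skeletal muscle, and which transcripts it binds there. Total RNA was sequenced from WT muscle (n = 3) and from muscle of IMP2 knockout mice (n = 3), and RNA recovered with an IMP2 antibody from WT (n = 2) and KO muscle (n = 2). The mice were 6 weeks old and had received a high-fat diet for 2 weeks. Total RNA libraries held 9691580 to 14809788 gene counts and IP libraries 917462 to 4037480. No label states that the libraries came from separate animals, so p-values measure the spread between these samples, part of which may be technical. The genotype is given as an IMP2 null in the sample labels and as a muscle-specific knockout in the series description.

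Igf2bp2, which encodes IMP2 (ENSMUSG00000033581, chromosome 16, 22059009 to 22163299, minus strand, GRCm38), was low in every library and was still counted in KO muscle. In total RNA it had 35, 37 and 48 counts in the WT libraries and 21, 19 and 21 in the KO libraries. The mean was 2.72 ± 0.419 CPM in WT and 2.13 ± 0.330 CPM in KO (SD, n = 3 each). The log2 difference was -0.36 ± 0.28 (SE), which did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.897). In the IP it had 28 and 4 counts in WT and 9 and 25 in KO. Counts cover the whole gene, so reads from a part left in the knockout allele are included. Reads from other cells of the tissue that keep the gene, as a muscle-specific knockout would leave, are included as well. The counts do not tell these apart. The relatives Igf2bp1 and Igf2bp3 and Hmga2, a gene that can drive Igf2bp2, were near the floor, with at most 2 counts in any library for Igf2bp1 and Hmga2. Igf2bp3 had 10, 10 and 8 counts in WT total RNA and 1, 4 and 4 in KO total RNA.

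In total RNA, Cish, a cytokine-induced inhibitor of cytokine signalling, had the smallest p of all genes and was higher in KO muscle, at 31.9 ± 8.82 CPM against 8.40 ± 1.96 CPM in WT (SD, n = 3 each). Dysf, a membrane repair protein, stood at 197 ± 12.7 against 121 ± 14.6 CPM, and Myl4, the embryonic and atrial myosin light chain, and Dchs1, a cadherin, were also higher. Prg4, the joint lubricant lubricin, was lower in KO (8.15 ± 3.43 against 21.8 ± 2.48 CPM), as were Bdh1, an enzyme of ketone body metabolism, Dgat2, which makes triglyceride, the peptide carrier Slc15a2 and the peroxisomal factor Pex6. None of these genes passed the test. The log2 differences were 1.92 ± 0.24 (SE) for Cish, 0.70 ± 0.15 for Dysf, 1.34 ± 0.32 for Myl4 and 0.95 ± 0.22 for Dchs1. They were -1.43 ± 0.28 for Prg4, -1.37 ± 0.29 for Bdh1, -0.97 ± 0.21 for Dgat2, -1.61 ± 0.36 for Slc15a2 and -0.69 ± 0.16 for Pex6. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.294 for Cish and 0.897 for the others. Cish (chromosome 9, 107296026 to 107302784) overlaps 2 antisense genes whose reads may not be separated. Scg3, a protein of secretory granules, differed by 2.68 ± 0.61, and by 1.81 without the KO library 1, the library with pancreatic islet transcripts described further on.

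Igf2 (chromosome 7, 142650766 to 142666816), the growth factor named in the study's title, had 322, 1147 and 414 counts in WT total RNA and 622, 1495 and 755 in KO. Its log2 difference was 1.14 ± 0.48 (SE) in the direction of higher KO. The neighbouring imprinted transcript H19 differed by 0.56 ± 0.37, Igf1 by 0.15 ± 0.28 and the receptor Igf1r by -0.01 ± 0.23. Ppara, the fatty acid-sensing nuclear receptor (chromosome 15, 85734983 to 85802819), had 112, 73 and 116 counts in WT and 40, 33 and 30 in KO, a log2 difference of -0.92 ± 0.25. By the same edgeR quasi-likelihood test, the Benjamini-Hochberg adjusted p was 0.897 for both Igf2 and Ppara, against unadjusted values of 0.0401 and 0.00487. Igf2 overlaps the antisense gene Igf2os.

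Of 13169 genes tested in total RNA, 0 passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was found for 569 (267 higher and 302 lower in KO), where chance gives 658 if genes are independent. DESeq2 gave 5 genes (Cish and Scg3 higher, Bdh1, Prg4 and Slc15a2 lower), limma-voom 0, and edgeR without a filter on low counts 64. The groups did not overlap for 627 genes higher and 639 lower in KO, 9.61% of genes, where chance gives 10%. Scaling by library size alone moved the median of all genes by -0.22.

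**Figure D1:**
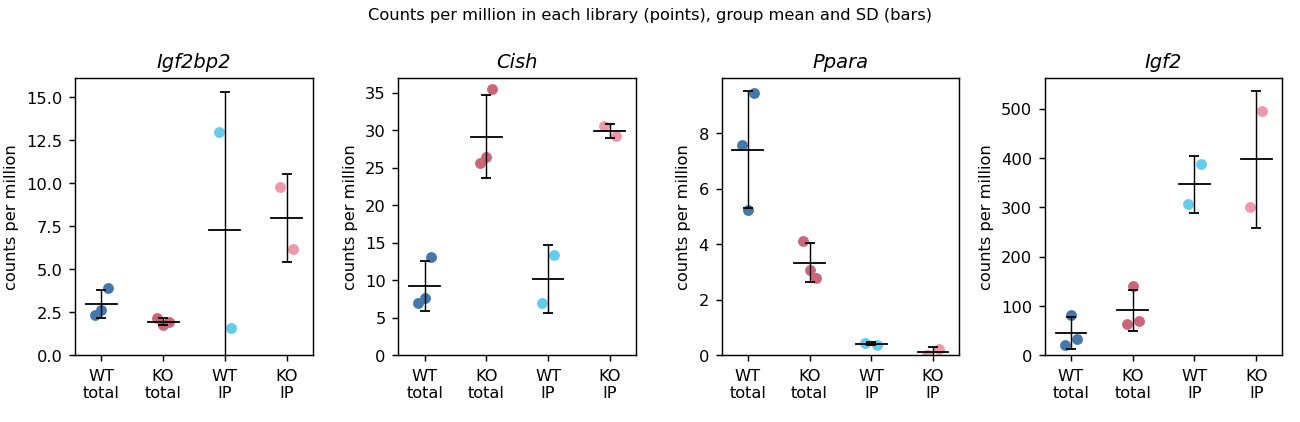
Level of Igf2bp2, Cish, Ppara and Igf2 in CPM (counts relative to library size) in every library (points), with the group mean and SD (bars), for total RNA and IP of WT and KO muscle. Igf2bp2 lay at 2.36 to 3.90 CPM in WT total RNA and 1.78 to 2.17 CPM in KO total RNA. The values shown are without TMM factors, so means, SDs and ranges differ from those on the TMM scale used for the text's means and the test.

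Genes of fatty acid uptake and oxidation lay lower together in KO total RNA, where 23 of 24 had a negative difference, with a median log2 of -0.32 (camera, adjusted p = 6.2e-08; adjusted p = 0.318 with an estimated correlation). Examples were Hadhb (-0.61 ± 0.16, SE, n = 3 per group), Cpt1b, which admits fatty acids to mitochondria (-0.61 ± 0.24), Cpt2 (-0.32 ± 0.14) and Lpl, which releases fatty acids from lipoproteins (-1.10 ± 0.33). Interferon response genes were lower for 21 of 22, with a median of -0.27 (camera, adjusted p = 2.1e-04; adjusted p = 0.601 with an estimated correlation). Among them were Oas2 (-0.92 ± 0.25), Irf7 (-0.62 ± 0.25), Ifi27l2a (-1.91 ± 0.81) and Mx1 (-0.87 ± 0.42). Genes of amino acid catabolism were lower for 16 of 19, with a median of -0.16 (camera, adjusted p = 0.00977; adjusted p = 0.601 with an estimated correlation). Dbt, a subunit of the branched-chain keto acid complex, stood at -0.40 ± 0.17 and Mut at -0.44 ± 0.22. The interferon list lost its call without the KO library 1 (median -0.15, adjusted p = 0.0543), and its median was also -0.15 without the WT library 1, which passed (adjusted p = 0.0403). The amino acid list lost its call without the KO library 3 (median -0.11, adjusted p = 0.0868).

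Lipogenesis and triglyceride storage genes were lower for 12 of 16, with a median of -0.77 (camera, adjusted p = 0.00359; adjusted p = 0.601 with an estimated correlation). Only Dgat2 passed when adjusted over the list alone, and 0 members passed over all genes. Scd1 (-4.05 ± 1.32, SE), Elovl6 (-3.82 ± 1.27) and Fasn (-3.39 ± 1.13), which make fatty acids, had the largest differences. Adipocyte markers were lower for 10 of 11, with a median of -0.68 (camera, adjusted p = 0.0295; adjusted p = 0.752 with an estimated correlation). Pck1 stood at -2.02 ± 0.88, the lipid droplet protein Cidec at -2.21 ± 1.01 and Plin4 at -0.50 ± 0.22. Both lists rested on the WT library 2, which held 2919 counts of Ucp1, the uncoupling protein of brown fat, against 1 to 53 in the other total RNA libraries. Adipocyte markers summed to 4593 CPM in that library and to 2593 to 3369 CPM in the others. Without it the lipogenesis median was -0.20 (adjusted p = 0.263), the adipocyte median 0.04 (adjusted p = 0.883), Scd1 -0.29, Fasn -0.37 and Dgat2 -0.72. The adipocyte list also lost its call without the KO library 2 (median -0.45, adjusted p = 0.193), and its median was -1.06 without the WT library 1, which passed.

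Fast fibre genes were higher in KO total RNA for 14 of 15, with a median log2 of 0.51 (camera, adjusted p = 7.7e-06; adjusted p = 0.601 with an estimated correlation). Pvalb, a calcium buffer of fast fibres, differed by 0.82 ± 0.30 (SE), Casq1 by 0.66 ± 0.26 and Tnnt3 by 0.64 ± 0.27, while Myh2, the myosin of type IIA fibres, went the other way (-0.74 ± 0.19). Calcium handling genes were higher for 14 of 17, with a median of 0.26 (camera, adjusted p = 5.1e-04; adjusted p = 0.601 with an estimated correlation). The calcium channel subunits Cacng1 and Cacna1s stood at 0.61 ± 0.24 and 0.47 ± 0.22. Genes of myogenesis and regeneration were higher for 16 of 18, with a median of 0.43 (camera, adjusted p = 3.5e-05; adjusted p = 0.318 with an estimated correlation). These included Dlk1 (1.55 ± 0.40), Myod1 (0.64 ± 0.18) and Mymk, the myoblast fusion protein (1.59 ± 0.67). Smooth muscle and pericyte markers were higher for 10 of 10, with a median of 0.37 (camera, adjusted p = 2.1e-04; adjusted p = 0.601 with an estimated correlation). The pericyte gene Rgs5 stood at 0.63 ± 0.19 and smooth muscle actin Acta2 at 0.66 ± 0.27. The fast fibre, calcium, myogenesis, smooth muscle and fatty acid lists passed in each of the 6 fits that left out 1 library, with the fast fibre median at 0.30 to 0.70 and the calcium median at 0.12 to 0.32. The lowest values came without the WT library 3, and the calcium median was 0.15 without the KO library 1.

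Cytosolic ribosomal protein genes were higher for 51 of 59 in KO total RNA, with a median of 0.27 (camera, adjusted p = 1.6e-05; adjusted p = 0.752 with an estimated correlation). Rpl7a stood at 0.51 ± 0.21 (SE), and Rpl32 and Rps2 at 0.60 ± 0.28 each. Many of these genes have pseudogene copies that can take their reads. Translation factors were higher for 25 of 31, with a median of 0.23 (camera, adjusted p = 0.00172; adjusted p = 0.714 with an estimated correlation). The elongation factor subunit Eef1g stood at 0.61 ± 0.21. Cell cycle genes were higher for 19 of 22, with a median of 0.44 (camera, adjusted p = 7.9e-05; adjusted p = 0.601 with an estimated correlation). The mitotic kinase Cdk1 stood at 1.13 ± 0.39, Cenpf at 1.07 ± 0.47 and Top2a at 1.09 ± 0.50. Endothelial markers were higher for 10 of 12 (median 0.24, camera, adjusted p = 0.00206; adjusted p = 0.601 with an estimated correlation), with Vwf at 0.51 ± 0.18. Glycolysis genes were higher for 12 of 15 (median 0.34, camera, adjusted p = 0.00359; adjusted p = 0.714 with an estimated correlation), with Pgk1 at 0.40 ± 0.18. Fibroblast and matrix genes were higher for 10 of 15 (median 0.31, camera, adjusted p = 0.00977; adjusted p = 0.805 with an estimated correlation). The collagen genes Col1a1 and Col6a3 stood at 0.68 ± 0.26 and 0.52 ± 0.21.

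The IGF axis list was higher for 11 of 14 genes (median 0.20, camera, adjusted p = 0.0250; adjusted p = 0.601 with an estimated correlation). Igfbp7, an IGF-binding protein, stood at 0.57 ± 0.24 (SE) and the signalling adaptor Irs1 at 0.52 ± 0.29. The list of mRNAs reported to be bound by IMP proteins was higher for 14 of 17 (median 0.18, camera, adjusted p = 0.0255; adjusted p = 0.601 with an estimated correlation). Its member with the smallest p, Ppara, went the other way (-0.92 ± 0.25). The cyclins Ccnd3 and Ccnd1 stood at 0.48 ± 0.17 and 0.45 ± 0.22, and Igf2 at 1.14 ± 0.48. With library size alone, which lowered the median of all genes, the medians of these lists were -0.05 and -0.03, and relative to all genes they stayed at 0.18 and 0.21. In all, 12 lists passed as higher and 5 as lower of 40 tested, and 0 passed with an estimated correlation. In every list that passed, 0 members passed over all genes, and apart from Dgat2 0 passed when adjusted over the list alone.

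Several of the higher lists rested on libraries numbered 3. The WT library 3 stood apart from the other total RNA libraries on the main axis of variation, at 48.8 where the others lay at -31.5 to 4.7, and its slow fibre genes summed to 729 CPM against 214 to 494 CPM. Without it the median and adjusted p were 0.12 and 0.169 for ribosomal proteins, 0.05 and 0.328 for translation factors and 0.07 and 0.703 for matrix genes. They were 0.14 and 0.306 for glycolysis, 0.02 and 0.306 for the IGF axis, and 0.09 and 0.306 for IMP-bound mRNAs. Without the KO library 3 they were 0.01 and 0.532 for ribosomal proteins, 0.15 and 0.246 for matrix genes, 0.12 and 0.145 for the IGF axis, 0.15 and 0.3 for IMP-bound mRNAs, and 0.20 and 0.0895 for the cell cycle. The glycolysis median was 0.17 without the KO library 3. Other calls ended while the median stayed within 1.5 times, for glycolysis without the KO library 1 (0.37, adjusted p = 0.0506), for endothelial markers without the WT library 1 (0.27, 0.0614) or the KO library 2 (0.17, 0.0834), and for IMP-bound mRNAs without the WT library 1 (0.22, 0.124) or the KO library 2 (0.23, 0.0743). Larger medians, all passing, were 0.39 for the IGF axis without the WT library 1 or the KO library 2, 0.39 for endothelial markers without the KO library 1 and 0.41 for ribosomal proteins without the WT library 2.

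**Figure D2:**
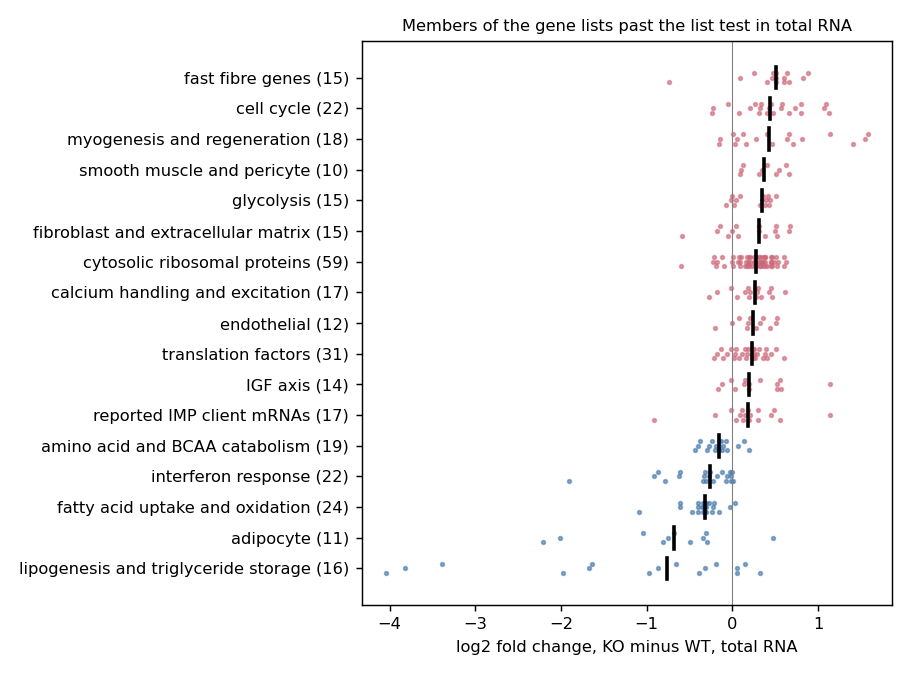
Log2 difference of KO minus WT total RNA for the members (points) of the 17 lists that passed the camera test with its preset correlation, with the list median (black bar). The fatty acid median lay at -0.32 and the fast fibre median at 0.51.

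Transcripts of other tissues stood out in single total RNA libraries. Pancreatic islet genes summed to 2161 CPM in the KO library 1 and to at most 2.15 CPM in the other total RNA libraries, and to 50.0 and 363 CPM in the WT IP and 445 and 178 CPM in the KO IP libraries. Ins2, which encodes insulin, had 11628 counts in the KO library 1 and 2 to 10 in the other total RNA libraries. Xist, the transcript of the inactive X chromosome, had 46 counts in the KO library 1 and at most 3 in the others, in mice given as male. Without both the KO library 1 and the WT library 2, 0 genes passed in total RNA, the lowest Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test was 0.0927, and the lipogenesis and adipocyte medians were -0.19 and 0.06.

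In the IP, WT was compared with KO, whose IP served as the background of the antibody, with the limit that Igf2bp2 was still counted in KO muscle and that the protein was not measured here. Trim54, a ring finger protein of striated muscle, stood higher in the WT IP, at 191 ± 20.8 against 80.6 ± 3.92 CPM (SD, n = 2 each), as did Nnat, Spp1, Selenok and Ankrd1. The nuclear transcript Neat1 stood lower in the WT IP, at 1499 ± 71.4 against 3994 ± 446 CPM, as did Rsrp1 (373 ± 70.6 against 1044 ± 182 CPM), the splicing kinase Clk1, the corneal and tendon proteoglycan Kera and Ccm2l. The log2 differences of WT minus KO were 1.23 ± 0.23 (SE) for Trim54, 1.84 ± 0.36 for Nnat, 5.18 ± 1.05 for Spp1, 1.29 ± 0.27 for Selenok and 1.57 ± 0.34 for Ankrd1. For the transcripts lower in WT they were -1.41 ± 0.23 for Neat1, -1.48 ± 0.24 for Rsrp1, -1.46 ± 0.26 for Clk1, -1.73 ± 0.32 for Kera and -1.38 ± 0.26 for Ccm2l. Igf2 differed by -0.05 ± 0.25, H19 by 0.51 ± 0.32, Igf1 by -0.08 ± 0.25 and Igf2bp2 by 0.02 ± 0.78. Ppara, with 1, 1, 0 and 1 counts, and Igf1r, with 8, 3, 2 and 12, were too low to test.

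No gene of 10730 passed edgeR's quasi-likelihood test in the IP comparison after Benjamini-Hochberg adjustment, with adjusted p = 0.0992 for Rsrp1 and Neat1 and 0.103 for Trim54. An unadjusted p under 0.05 was found for 1128 genes (518 higher and 610 lower in WT) where chance gives 536.5. DESeq2 gave 45 genes, limma-voom 3 (Clk1, Neat1 and Rsrp1), the robust edgeR fit 24 and edgeR without a filter on low counts 103. Leaving out the WT library 1, the WT library 2, the KO library 1 or the KO library 2 gave 136, 59, 146 and 13 genes. Scaling by library size alone moved the median of all genes by -0.14.

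The list of mRNAs reported to be bound by IMP proteins was higher in the WT IP for 8 of 16 (median 0.007, camera, adjusted p = 0.340). For the IGF axis this held for 3 of 11 (median -0.08, camera, adjusted p = 0.645). Neither list passed here or in the interaction (camera, adjusted p = 0.0913 and 0.312). In the interaction, 13 of 18 IMP-bound mRNAs were higher and 5 lower (median 0.25, mean -0.08). Ucp1, the brown fat gene that stood out in the WT total RNA library 2, is a member and among those with the smallest p there, so this list result is affected by that library. Trim54 passed when adjusted over the list of IMP-bound mRNAs alone. Subunits of the respiratory chain were higher in the WT IP than in the KO IP. For complex I this held for 33 of 35 genes, with a median log2 of 0.49 (camera, adjusted p = 7.7e-08; adjusted p = 0.834 with an estimated correlation). When adjusted over the list alone 6 genes passed, among them Ndufa13 (0.75 ± 0.21, SE, n = 2 per group), Ndufb7 (0.75 ± 0.21) and Ndufb6 (1.05 ± 0.32). Complexes II to IV were higher for 22 of 25 (median 0.50, camera, adjusted p = 1.5e-05; adjusted p = 0.834 with an estimated correlation), with Cox6b1 at 0.71 ± 0.22. ATP synthase subunits were higher for 12 of 13 (median 0.36, camera, adjusted p = 0.0162; adjusted p = 0.834 with an estimated correlation). Cytosolic ribosomal protein genes were higher for 46 of 52 (median 0.45, camera, adjusted p = 7.7e-08; adjusted p = 0.834 with an estimated correlation). Rpl7 stood at 0.87 ± 0.25 and Rps7 at 1.48 ± 0.47. Mitochondrial ribosomal proteins (33 of 40, median 0.33, camera, adjusted p = 0.00154), fast fibre genes (13 of 15, median 0.25), heat shock proteins (13 of 16, median 0.23) and translation factors (23 of 31, median 0.23, camera, adjusted p = 0.0162 for these last lists) were also higher, with adjusted p = 0.834 each with an estimated correlation. Hspb7, a small heat shock protein, differed by 0.94 ± 0.24, Mrps28 by 0.99 ± 0.33, Actn3 by 0.64 ± 0.25 and Eif3f by 0.67 ± 0.21.

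Lists of matrix, erythroid, tendon, endothelial and Schwann cell genes and of nuclear RNAs were lower in the WT IP than in the KO IP, whereas adipocyte (7 of 10 higher, median 0.17), brown adipocyte (4 of 4, 0.35), macrophage (6 of 11, 0.26), smooth muscle (4 of 10, -0.05) and satellite cell markers (3 of 7, -0.04) did not pass. Fibroblast and matrix genes were lower for 15 of 15 (median -0.70, camera, adjusted p = 3.4e-06; adjusted p = 0.834 with an estimated correlation). When adjusted over the list alone 11 passed, such as Col1a2 (-1.07 ± 0.24, SE), Col1a1 (-1.05 ± 0.25), Fbn1 (-0.83 ± 0.23) and Col3a1 (-0.83 ± 0.23). Erythroid genes were lower for 4 of 4 (median -1.31, camera, adjusted p = 2.6e-04; adjusted p = 0.834 with an estimated correlation). All 4 passed when adjusted over the list alone, with Hbb-bt at -1.82 ± 0.40 and Hbb-bs at -1.57 ± 0.35. Tendon genes (6 of 7, median -1.24, camera, adjusted p = 0.0142), nuclear retained RNAs (6 of 7, median -1.11, adjusted p = 0.0148), endothelial markers (12 of 12, median -0.42, adjusted p = 0.0162) and Schwann cell markers (8 of 8, median -0.59, adjusted p = 0.0121) were lower, with adjusted p = 0.834 each with an estimated correlation. When adjusted over the list alone, 4 tendon genes, 4 nuclear RNAs and 3 endothelial genes passed, including Chad (-2.59 ± 0.60), Meg3 (-1.11 ± 0.30) and Kdr (-1.27 ± 0.32). Over all genes 0 members of any list passed.

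Of the 14 lists that passed in the IP comparison, ribosomal proteins, complex I, matrix and erythroid genes passed whichever library was left out. Without the KO IP library 2, the deepest, 5 of the 14 passed, the tendon list with these 4, and 1 other list. Complex I then had a median of 0.33. The median and adjusted p of lists that did not pass were 0.33 and 0.132 for complexes II to IV, 0.24 and 0.478 for ATP synthase and 0.23 and 0.385 for mitochondrial ribosomes. They were 0.04 and 0.964 for fast fibre genes, 0.16 and 0.387 for heat shock proteins, 0.17 and 0.457 for translation factors, -0.13 and 0.457 for endothelial, -0.72 and 0.0667 for Schwann and -0.93 and 0.344 for nuclear RNAs. Without the KO IP library 1 the tendon median was -0.25 (adjusted p = 0.418), while the fast fibre median was 0.70 and the heat shock median 0.34, both passing. Without the WT IP library 1 the Schwann (median -0.29, adjusted p = 0.217), nuclear (-0.70, 0.0673), endothelial (-0.32, 0.0944), heat shock (0.38, 0.0633) and translation lists (0.28, 0.0633) did not pass, and the fast fibre median was 0.42, which passed. Without the WT IP library 2 the ATP synthase (median 0.18, adjusted p = 0.343), mitochondrial ribosome (0.16, 0.302), fast fibre (0.12, 0.351), heat shock (0.18, 0.0566), endothelial (-0.44, 0.0501) and translation lists (0.23, 0.154) did not pass. The tendon median was then -0.76 and the Schwann median -0.89, both passing. Tendon genes summed to 476 and 333 CPM in the WT IP and 1288 and 583 CPM in the KO IP, and erythroid genes to 172 and 315 against 549 and 930 CPM.

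Against total RNA of the same genotype, the IP differed widely in both genotypes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2534 genes rose and 2791 fell in the WT IP and 2551 rose and 2700 fell in the KO IP, of 14399 tested. Of these, 1544 rose and 1924 fell in both, where independent lists would share 449 and 523, and 5 changed in opposite directions. Across genes, which are not independent replicates, the log2 ratios of both genotypes had a Pearson r of 0.64. Both contrasts share no library but share the fit's estimate of spread. With library size alone the KO calls became 4267 higher and 1439 lower, as the median of all genes moved by 0.43, and without the KO IP library 2 the KO contrast gave 2148 genes.

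**Figure D3:**
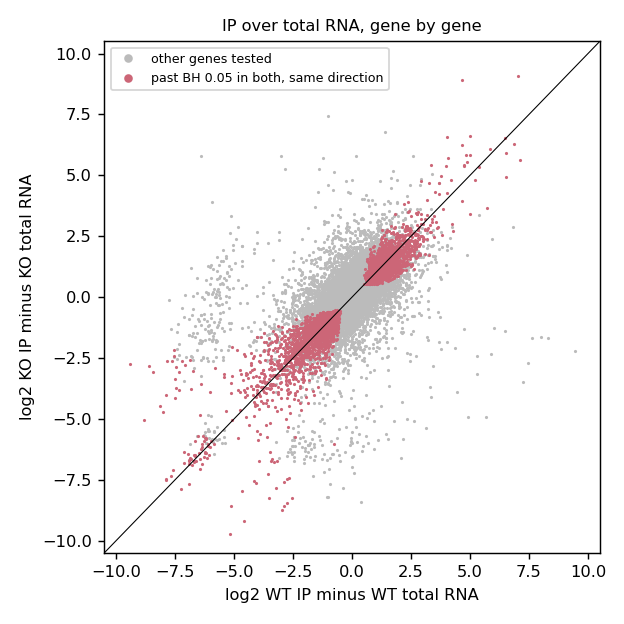
Log2 ratio of IP over total RNA for 14399 genes (points) in WT (x axis) and KO muscle (y axis), with the line of equality. Red points passed the test in the same direction in both genotypes, 1544 higher and 1924 lower.

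Igf2 rose in the IP over total RNA in WT by 2.82 ± 0.47 on the log2 scale (SE, adjusted p = 4.0e-04, edgeR quasi-likelihood test, Benjamini-Hochberg), from 46.8 ± 36.2 to 331 ± 75.3 CPM (SD). In KO it rose by 1.72 ± 0.46 (adjusted p = 0.00972 by the same edgeR quasi-likelihood test and Benjamini-Hochberg adjustment), a call that ended without the KO IP library 2 (1.33, adjusted p = 0.153). Igf1 rose in both, by 1.99 ± 0.30 and 1.91 ± 0.30. H19 rose in WT (1.22 ± 0.41), with a Benjamini-Hochberg adjusted p of 0.0319 by edgeR's quasi-likelihood test, and did not pass in KO (0.14 ± 0.42). Without the WT total RNA library 1 or 3, or the WT IP library 1 or 2, that adjusted p of H19 was 0.0768, 0.0787, 0.0653 and 0.230. Ppara fell in both, from 301 counts in WT total RNA to 2 in the WT IP, a ratio of 17.3 (95% interval 4.74 to 143), and from 103 to 1 in KO, a ratio of 16.4 (2.88 to 654). Igf1r fell by 1.47 in WT and by 1.39 in KO. The difference stayed negative but no longer passed in WT without the WT IP library 2 (-0.97, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.171) and in KO without the KO IP library 2 (-1.69, 0.197), and several other omissions also ended these calls. Igf2bp2 itself differed by 1.18 ± 0.57 in WT and 1.47 ± 0.60 in KO, and neither passed. The differences between genotypes in these ratios, tested as an interaction, were 1.11 ± 0.66 for Igf2, 1.08 ± 0.59 for H19 and 0.28 ± 1.19 for Ppara, and none passed.

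The named transcripts that rose most in the WT IP included Ins1 (8.03 ± 2.55, log2 ± SE) and Ins2 (7.64 ± 2.34), the islet transcripts described above, calls that ended without the WT total RNA library 3 (7.66 and 7.38) or the WT IP library 2 (6.02 and 5.30). Others were the chemokine Ccl5 (4.67 ± 0.88), Nr2c2ap (3.85), Tmem178 (3.81), Tmsb10, an actin-binding peptide (3.46 ± 0.30), the mast cell protease Tpsb2 (3.40 ± 0.37), Gata3 (3.36), Laptm5 (3.32) and Platr32 (3.70), which did not pass without the WT IP library 1 (2.45). In the KO IP, the brown fat genes Ucp1 (7.45 ± 2.46) and Cidea (4.41) and Apoc1 (5.72) rose. Each omission of a KO library ended these calls, as for Ucp1 without the KO IP library 1 (6.94). Ucp1 stood at 7.87 and 69.1 CPM in the WT IP and 48.0 and 24.0 CPM in the KO IP. The WT total RNA library 2 held 209 CPM of Ucp1 and the KO total RNA library 1 held 1200 CPM of Ins2. The ratios of islet and brown fat transcripts to total RNA therefore do not compare the genotypes. Ccl5 (3.93), Platr32 (4.67) and Xntrpc (3.89) rose but not without the KO IP library 2 (1.47, 3.02 and 2.91), while Nr2c2ap (3.61), Trf (3.51), Efna4 (3.49) and the interferon gene Ifi44 (3.44 ± 0.32) kept their calls in every omission.

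Transcripts with 0 counts in an IP gave lower bounds from a floor of 3 counts over the group, without the counting error of total RNA. In the WT IP, Mir5125 was at least 17.2-fold lower than in total RNA, the nucleotidase Nt5c1a 11.3-fold, Kbtbd4 8.71-fold and the mitotic kinase Wee1 7.11-fold, each as a minimum. Cyb5d1 was lower by at least 5.85-fold, the ephrin receptor Epha4 5.73-fold, Trmt13 5.47-fold, Rfx3 5.05-fold, Prdm10 4.62-fold and Fgd1 4.59-fold. In the KO IP, Vash1 was at least 19.6-fold lower, the insulin receptor substrate Irs2 13.2-fold, the glycine carrier Slc6a9 9.61-fold, and Ston1 8.65-fold. The bound was 7.85-fold for Zfp366, and Kif26b was at least 7.70-fold lower, Slc39a7 6.90-fold, Syne3 and Apcdd1 6.85-fold and the muscle growth factor Fgf6 6.53-fold. Kif26b, Apcdd1 and Fgf6 did not pass without the KO IP library 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0884, 0.149 and 0.0696).

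Ribosomal protein transcripts were raised in the IP of both genotypes. Numbers of list members given for the IP against total RNA are those that passed edgeR's test over all genes, and they rose by at most 2 when adjusted over the list alone. In WT, 47 of 59 rose and 1 fell over all genes (48 and 2 when adjusted over the list alone), with a median log2 of 1.69 (camera, adjusted p = 2.0e-13; adjusted p = 0.952 with an estimated correlation). Rps18 rose by 2.61 ± 0.22 (SE). In KO, 33 rose and 4 fell, with a median of 0.97 (camera, adjusted p = 1.1e-05; adjusted p = 0.839 with an estimated correlation). Enzymes of the TCA cycle were depleted, with 16 of 21 passing as lower in WT (median -1.19, camera, adjusted p = 6.4e-06; adjusted p = 0.952 with an estimated correlation) and 15 in KO (median -1.11, camera, adjusted p = 3.9e-06; adjusted p = 0.839 with an estimated correlation). In WT, Pdha1, of the pyruvate dehydrogenase complex, stood at -2.28 ± 0.25 and Fh1, fumarate hydratase, at -1.84 ± 0.24. Interferon genes were raised, 10 of 22 in WT (median 0.72, camera, adjusted p = 0.00252; adjusted p = 0.952 with an estimated correlation) and 16 in KO (median 1.41, camera, adjusted p = 1.1e-05; adjusted p = 0.839 with an estimated correlation). Matrix genes were raised, 9 of 15 in WT (median 0.87, camera, adjusted p = 0.0173; adjusted p = 0.965 with an estimated correlation) and 10 in KO (median 0.99, camera, adjusted p = 3.2e-04; adjusted p = 0.839 with an estimated correlation). Genes of amino acid catabolism were lower, 9 of 19 in WT (median -0.47, camera, adjusted p = 0.0173; adjusted p = 0.952 with an estimated correlation) and 11 in KO (median -0.68, camera, adjusted p = 0.0333; adjusted p = 0.839 with an estimated correlation).

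In the WT IP, fatty acid genes also passed as lower, 12 of 24 (median -0.55, camera, adjusted p = 0.00417; adjusted p = 0.952 with an estimated correlation), with Acadvl at -4.08 ± 0.43 (SE). In KO 12 were lower as well (median -0.65, camera, adjusted p = 0.0807), and the interaction did not pass (0.0708). Smooth muscle markers passed as higher, 7 of 10 (median 1.00, camera, adjusted p = 0.00666; adjusted p = 0.952 with an estimated correlation), with Tagln at 2.27 ± 0.27. In the KO IP, fast fibre genes (10 of 15, median -1.65, camera, adjusted p = 3.2e-04), sarcomere genes (12 of 21, median -1.11, adjusted p = 0.00127), calcium handling genes (11 of 17, median -1.33, adjusted p = 0.00251) and glycogen genes (7 of 13, median -0.82, adjusted p = 0.0335) passed as lower, with adjusted p = 0.839 each with an estimated correlation. In WT these lists did not pass, with 6, 9, 8 and 7 genes lower, 1, 3, 5 and 0 genes higher, and medians of -0.43, -0.35, -0.61 and -0.82. As an interaction, the fast fibre, calcium handling and smooth muscle lists passed with the preset correlation, as given with that contrast, and the sarcomere (camera, adjusted p = 0.0758) and glycogen lists (0.798) did not. Against the direction of their lists, 1 fatty acid gene and 1 amino acid gene passed in WT, and 2 amino acid genes, 1 sarcomere gene and 1 calcium handling gene in KO. Myh1, the myosin of type IIX fibres, fell by 3.20 ± 0.44. Without the WT IP library 1, the fatty acid (median -0.34, adjusted p = 0.0872), amino acid (-0.49, 0.191) and matrix lists (0.68, 0.0885) of WT and the glycogen and amino acid lists of KO (medians -0.84 and -0.69, 0.0508 each) did not pass. Without the WT IP library 2, the fatty acid and amino acid medians of WT were -0.94 and -0.76, both passing. The matrix list of WT did not pass without the WT total RNA library 3 (0.70, adjusted p = 0.0640). In KO the glycogen list did not pass without the KO total RNA library 1 (-0.62, adjusted p = 0.0586) or the KO IP library 2 (-0.63, 0.158), nor the amino acid list without the KO IP library 2 (-0.48, 0.213).

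The interaction asked which transcripts were enriched over total RNA more in the WT IP than in the KO IP. Of 14399 genes, 1 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Prps1l3, a relative of phosphoribosyl pyrophosphate synthetase (5.28 ± 0.71, log2 ± SE, adjusted p = 0.0415). Prps1l3 (ENSMUSG00000079104, chromosome 12, 57230412 to 57239882) had 17 and 18 counts in the WT IP and 0 and 1 in the KO IP, a ratio in CPM of 36.9 (95% interval 6.19 to 1497). It was not enriched in the WT IP, where total RNA exceeded the IP by a ratio of 1.63 (1.15 to 2.36), against 51.9 (9.25 to 2056) in KO. These ratios are without TMM factors, unlike the log2 difference of the test. In total RNA it stood at 12.0 ± 0.632 CPM in WT and 12.2 ± 1.15 CPM in KO (SD, n = 3 each). It lies inside Mipol1 on the same strand, and how shared reads were counted was not given in the sources used here. Leaving out any of the 10 libraries ended its call (adjusted p = 0.0581 to 0.418, edgeR quasi-likelihood, Benjamini-Hochberg). The fitted log2 difference was 5.01 to 5.33 in these fits, except 8.87 without the KO IP library 2, where the remaining KO IP library had 0 counts, so that 8.87 depends on the prior count and is no bound. Among genes lower in this contrast that met the conditions for naming, those with the smallest p were Aldh9a1 (-2.06 ± 0.41), Eif2s3y (-1.85 ± 0.37), Hars2 (-1.35 ± 0.28), Palld (-1.50 ± 0.31) and Nlrc5 (-2.86 ± 0.59). None of these passed. An unadjusted p under 0.05 was found for 1703 genes, where chance gives 719.95 if genes are independent. This excess has the limit given for the IP comparison. DESeq2 gave 17 genes and limma-voom 0.

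As lists, ribosomal proteins (51 of 59 higher, median log2 0.76, camera, adjusted p = 6.1e-07), complex I (33 of 35, median 0.54, 7.1e-05), complexes II to IV (22 of 25, median 0.46, 0.00183) and fast fibre genes (14 of 15, median 0.91, 2.5e-04) were higher in this contrast. So were translation factors (24 of 31, median 0.49, 0.00343), calcium handling (14 of 17, median 0.40, 0.00343) and mitochondrial ribosomal proteins (36 of 42, median 0.46, 0.00343). The same held for ATP synthase (15 of 15, median 0.51, 0.0192), glycolysis (15 of 15, median 0.42, 0.0193), heat shock proteins (13 of 17, median 0.37, 0.0277) and smooth muscle markers (10 of 10, median 0.47, 0.0341). Interferon genes were lower for 19 of 22 (median -0.57, camera, adjusted p = 0.0277). The adjusted p was 0.847 to 0.855 for all 12 lists with an estimated correlation. Cox7c (2.25 ± 0.51, SE) and Eef1g (1.30 ± 0.33) passed when adjusted over the list alone, and 0 members over all genes. The contrast contains the difference in total RNA. For smooth muscle markers the median was -0.05 in the IP as WT minus KO and 0.37 in total RNA as KO minus WT. These medians were 0.25 and 0.51 for fast fibre genes and 0.17 and 0.34 for glycolysis. They were 0.49 and 0.11 for complex I and 0.45 and 0.27 for ribosomal proteins. Without the KO IP library 2, 0 lists passed, with medians of 0.67 for ribosomal proteins (adjusted p = 0.0573), 0.44 for complex I (0.155), 0.29 for complexes II to IV (0.320), 0.59 for fast fibre genes (0.260), 0.37 for translation factors (0.260) and 0.52 for calcium handling (0.328). Mitochondrial ribosomal proteins were then at 0.29 (0.432), ATP synthase at 0.38 (0.320), glycolysis at 0.28 (0.632), heat shock proteins at 0.37 (0.328), interferon genes at -0.50 (0.260) and smooth muscle markers at 0.48 (0.260). Of the 12 lists, without the WT IP library 2 only ribosomal proteins, complex I and fast fibre genes passed, beside 3 lists outside the 12. Those lost had medians of 0.39 for complexes II to IV (adjusted p = 0.0693), 0.29 for ATP synthase (0.182), 0.32 for mitochondrial ribosomal proteins (0.182), 0.27 for glycolysis (0.182), 0.41 for calcium handling and 0.60 for translation factors (0.0532 each), 0.32 for heat shock proteins (0.113), -0.29 for interferon genes (0.161) and 0.44 for smooth muscle markers (0.169). Without the KO total RNA library 3, medians were 0.44 for ribosomal proteins, 0.30 for complex I and 0.24 for complexes II to IV, which passed, and 0.23 for ATP synthase (adjusted p = 0.106) and 0.28 for mitochondrial ribosomal proteins (0.0758), which did not. Without the WT total RNA library 3, ATP synthase (0.44, adjusted p = 0.0640), glycolysis (0.21, 0.0959) and heat shock proteins (0.37, 0.0631) did not pass. Interferon genes did not pass without the WT total RNA library 1 (-0.42, adjusted p = 0.117) or the KO total RNA library 1 (-0.44, 0.130), nor heat shock proteins without the WT IP library 1 (0.44, 0.0584). Smooth muscle markers lost their call in 7 of 10 omissions, with medians of 0.27 to 0.48. Without the KO IP library 1, medians were 0.65 for glycolysis, 0.71 for calcium handling and 0.56 for heat shock proteins, all passing. Library size alone moved the median of all genes by -0.37.

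Transcripts recovered more in the WT IP than in the KO IP were then examined in total RNA. As none had passed, the 200 with the largest statistic were taken, of which 199 were tested in total RNA, and 153 lay higher and 46 lower in KO. Their median log2 was 0.14, against -0.01 for the other genes (camera, p = 4.8e-05; p = 0.443 with an estimated correlation of 0.34). The median was 0.04 without the WT library 3, with a camera p of 0.801, and 0.03 without the KO library 3, with a camera p of 0.362.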

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

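Of the tests in this part, those on islet transcripts, on brown fat transcripts and on IMP2 left in the knockout were chosen after the results were seen, and those on transcript length, on RNA bound without IMP2 and on other splits before.

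Prps1l3 stood out because its ratio of IP to total RNA differed between genotypes by 5.28 on the log2 scale in the test of that difference, although total RNA exceeded the IP in both, by a ratio of 1.63 (95% interval 1.15 to 2.36) in WT and 51.9 (9.25 to 2056) in KO. The reads aligned to several places, which no comparison used, made up 42.6% of reads in the WT IP and 38.2% in the KO IP, above the 33.2% and 34.4% in total RNA of WT and KO.

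Pancreatic islet transcripts were abundant in the KO total RNA library 1 and present in all IP libraries of both genotypes. Whole pancreas carried along would bring more acinar than islet transcripts, but the acinar sum was 0.00267 of the islet sum. Expression switched on by loss of IMP2 was also argued against, as the other KO total RNA libraries reached at most 0.0996% of the level in library 1. The islet genes kept nearly the same order of abundance in library 1 and in the IP libraries (Spearman 0.959 over 14 genes, which are not independent replicates), and the IP sum was 7.21% to 12.7% of library 1 gene by gene. A candidate source is therefore islet RNA, or reads of an islet library, from outside the muscle, and the data do not tell RNA from reads.

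Brown fat transcripts such as Ucp1 stood out in the WT total RNA library 2. Thermogenic genes switched on in muscle without fat cells would leave general adipocyte genes level, but 9 of 11 were highest in this library. Their median log2 excess over the other total RNA libraries was 1.56 (SD 1.25 between genes), as brown fat carried along with the muscle may give. Such fat is not the whole source of the lower fatty acid oxidation list in KO, whose median stayed at -0.31 without this library. A biological difference of this animal's muscle was not tested. Ucp1 was also counted in every IP library, at 3.76% and 33.0% of its CPM in the WT total RNA library 2 for WT. For KO these shares were 22.9% and 11.5%. Brown fat RNA or reads from outside the muscle, the candidate given for islet transcripts, were not tested here and stay open.

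The content of the IP was much alike in WT and KO, with a correlation across genes of 0.64 for the ratio of IP to total RNA. Transcript length and GC content were argued against as the whole cause, since the correlation was 0.632 after their trends were removed and 0.639 before over the same genes. RNA recovered without IMP2 in both IPs may contribute, and it stays open, because 10.3% of transcripts raised in the WT IP were higher in WT than in KO at an unadjusted p under 0.05, against 2.82% lower, and the WT libraries are shared. IMP2 left in KO muscle also stays open, with Igf2bp2 at a log2 difference of -0.36 and no measure of the protein. These 2 sources cannot be told apart here. Other differences between IP and total RNA libraries, such as depth, reads aligned to several places and transcripts of other tissues, were not tested as sources.

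The 6 total RNA libraries allow 10 splits into groups of 3, too few for a share under 0.05. For genes that passed, the real split gave 0 and the highest other 1, so that all 10 splits were as large by construction and this comparison says nothing. For lists, the real split gave 17 and the highest other 21, with 5 of the 10 splits, the real one included, at least as large as the real one. For the IP transcripts, the real median was 0.14 and the highest other 0.28 in absolute value, with 6 of the 10 splits, the real one included, at least as large.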

How the results depend on the processing

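The robust fit, the fit without both the WT total RNA library 2 and the KO total RNA library 1, and the list alternatives for the IP comparison and for IP against total RNA were chosen after the data were seen. Results that answer a comparison kept their side of the threshold, or stayed within 1.5 times, in 110 recomputed values, moved in 44 and no longer passed in 4. Named genes and lists kept direction and side in 5573 values, gained a call in 166, lost it in 261 and turned in 38. Where 1 IP library of a group was left out, the remaining one was assumed to vary like the other groups. Leaving out mitochondrially encoded genes was not run because all 37 have 0 counts. The set from the interaction (1 gene) gave no value, the 200 top transcripts were the set already used, and a fold of at least 2 left 0 genes. In the shallowest IP library a count of 0 allows up to 3.27 CPM, so weaker transcripts are not measured there. The cause was not tested for any of the changes below.

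Total RNA gave 64 genes without a filter and 5 by DESeq2. The IP comparison gave 1 gene with library size alone, 103 without a filter, 17 at a mean of 1 CPM, 45 by DESeq2, 3 by limma-voom, 24 with the robust fit, 1 in the fit of 10 libraries, and 13 to 146 with a library left out. The interaction gave 0 genes with library size alone, by limma-voom and without both libraries, 263 without a filter, 17 by DESeq2, and 0 to 1 with a library left out. KO IP against total RNA gave 2148 to 5706 genes with a library left out. With an estimated correlation 0 lists passed in any comparison. With fry 0 passed in total RNA, the IP comparison and the interaction, and 12 in IP against total RNA of each genotype. With a library left out, 6 to 20 lists passed in the IP comparison, 0 to 15 in the interaction, 4 to 10 in WT IP and 7 to 14 in KO IP against total RNA. The median of the IP transcripts in total RNA stayed 0.14 with the estimated correlation (p of 0.443) and fry (p of 0.502), neither of which passed, and was 0.025 to 0.25 with a library left out.

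Same-numbered libraries of WT and KO did not vary together (correlations of 0.116, -0.135 and -0.337 in total RNA and -0.0738 in the IP). In the IP only the sign of this value could vary, and differently numbered libraries gave 0.0738. Total RNA was not compared with the IP in this way, so whether both came from the same animal stays open. No label says that the numbers pair libraries, so they were not taken as pairs. With a replicate block, total RNA gave 0 genes, the IP comparison 28 and the interaction 0, the IP transcripts had a median of 0.14, and Igf2bp2 in the IP turned to -0.52.

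Values that turned belonged to genes near 0, to genes with few counts or to fat markers. With a library left out, in total RNA the adipocyte median was -1.06 to 0.044, Cidec -2.78 to 0.25, Igf1 -0.18 to 0.35 and Igf1r -0.15 to 0.11. In the IP, Igf1 was -0.46 to 0.22, Igf2 -0.32 to 0.31 and Igf2bp2 -2.04 to 0.88. In the interaction, Igf1 was -0.30 to 0.41, Igf1r -1.01 to 0.55, Igf2bp2 -2.37 to 0.59 and Ppara -0.00042 to 3.87. In IP against total RNA, Igf2bp2 was -0.91 to 1.93 in WT and H19 -0.57 to 0.59 in KO. With library size alone Igf1 was -0.067 in total RNA and -0.28 in the interaction, Igf2bp2 -0.086 in the IP and Ppara -0.11 in the interaction, each above the shift of the median of all genes under that scaling (-0.22 in total RNA, -0.14 in the IP and -0.37 in the interaction), so relative to all genes none of these turned. By limma-voom Igf2bp2 was -0.40 in the IP and Ppara -0.20 in the interaction. Without both libraries Cidec was 0.28, Pck1 0.063 and Igf1r 0.13 in total RNA, Igf1r 0.066 and Ppara -0.057 in the interaction, and H19 -0.075 in KO IP against total RNA.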

Other observations

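The comparisons in this part of single named genes across fits, of genes with 0 counts in the IP, and of islet, liver, keratinocyte and Ucp1 levels were chosen after the results were seen, whereas the gene lists were fixed earlier.

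Several lists of energy metabolism and muscle structure did not pass in total RNA. In KO, the median log2 was 0.11 for complex I (24 of 35 higher), 0.01 for complexes II to IV (13 of 25), 0.18 for ATP synthase (13 of 15), 0.09 for mitochondrial ribosomal proteins (29 of 42), -0.05 for the TCA cycle (6 of 21) and 0.01 for glycogen metabolism (7 of 13), with camera adjusted p from 0.0823 to 0.630. PPAR targets had a median of -0.19, with 15 of 22 lower (camera, adjusted p = 0.0587), and the lipid droplet protein Plin5 stood at -0.63 ± 0.23 (SE). Slow fibre genes had a median of 0.01 (7 of 13 higher, adjusted p = 0.420), sarcomere genes 0.10 (14 of 21, 0.233), atrophy genes -0.01 (9 of 19, 0.708) and denervation genes 0.01 (7 of 13, 0.559). Mstn, the brake on muscle growth, differed by 0.51 ± 0.17. Scaling by library size alone lowered all genes together, and relative to all genes the medians above 0 kept their sign, except that of slow fibre genes, which was -0.06.

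Further lists of stress, signalling and other cell types did not pass in total RNA either. Medians were 0.06 for the unfolded protein response (11 of 18 higher, camera, adjusted p = 0.458), 0.06 for heat shock proteins (10 of 17, 0.520), -0.01 for immediate early genes (9 of 19, 0.756), -0.03 for the circadian clock (7 of 16, 0.639) and -0.03 for the Wnt pathway (12 of 25, 0.630). Macrophage markers were lower for 12 of 12 (median -0.20, camera, adjusted p = 0.208) and satellite cell markers higher for 9 of 9 (median 0.15, 0.0731). Schwann cell markers had a median of 0.54 (7 of 10 higher, 0.335), erythroid genes -0.05 (2 of 5, 0.0587), tendon genes -0.01 (4 of 8, 0.469), nuclear RNAs -0.21 (3 of 7, 0.552) and brown adipocyte markers -0.18 (1 of 4, 0.552). Cidea, highest in the WT library 2, passed when adjusted over the brown adipocyte list alone (-5.57 ± 1.55, SE). The lists of IMP family genes, mitochondrially encoded mRNAs, neutrophils, T and B cells and small structural RNAs had fewer than 3 tested members. The direction of the camera test differed from the sign of the median for glycogen, immediate early, Wnt, tendon and erythroid genes.

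Cish was also higher in the KO IP, at 30.5 and 29.2 CPM against 6.95 and 13.3 CPM in the WT IP, a KO minus WT log2 of 1.38 ± 0.43 (SE) that did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.265). Dysf (0.27 ± 0.24) and Dchs1 (0.46 ± 0.40) were likewise higher in KO in both. Bdh1 (-0.27 ± 0.69), Dgat2 (-0.34 ± 0.28) and Pex6 (-0.26 ± 0.25) were lower in KO in both. Myl4 (-0.59 ± 0.48) and Scg3 (-0.30 ± 0.71), higher in KO total RNA, went the other way in the IP. So did Prg4 (0.60 ± 0.76) and Slc15a2 (0.53 ± 0.42), lower in KO total RNA. None of these differences passed in the IP. Of the transcripts lower in the WT IP, Rsrp1, Neat1 and Clk1 stood at 0.89 ± 0.48, 0.76 ± 0.49 and 0.43 ± 0.28 as WT minus KO in total RNA, the opposite direction. Across 10663 genes, which are not independent replicates, the WT minus KO difference in the IP had a Pearson r of -0.106 and a Spearman rho of -0.186 with that in total RNA.

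Longer transcripts were recovered less in the IP of both genotypes, with the median log2 of IP over total RNA going from 0.39 in the fifth of genes with the shortest transcripts to -0.47 in the longest in WT, and from 0.28 to -0.34 in KO. The differences between genotypes also varied with these traits. The Spearman rho over genes of WT minus KO in the IP was -0.140 with length and 0.087 with GC content. For KO minus WT in total RNA it was -0.099 and 0.228. The list tests did not take length or GC content into account. Of 7988 genes at 10 CPM or more in total RNA, 5, 4, 8 and 2 had 0 counts in the WT IP libraries 1 and 2 and the KO IP libraries 1 and 2, where depth alone gives at most 0.0345.

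Erythroid genes summed to 149 CPM in the WT total RNA library 2 and 96.2 CPM in the KO total RNA library 3, and to 30.1 to 49.2 CPM in the other total RNA libraries. Liver transcripts summed to at most 22.7 CPM in total RNA and 54.5 CPM in the IP, and keratinocyte transcripts to at most 8.24 CPM. Ucp1 in the IP libraries stood at 3.76% and 33.0% of its CPM in the WT total RNA library 2 for WT and 22.9% and 11.5% for KO, and the islet sum at 2.32%, 16.8%, 20.6% and 8.23% of that in the KO total RNA library 1.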
